A study of Mus musculus with 30 samples.

How the data were processed

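RNA of mouse RPE-choroid eyecups was measured in 30 libraries, an Input and a Positive (GFP-captured, ribosome-bound) library of each of 15 pools of 4 eyecups of 2 mice, harvested in the morning after tamoxifen induction. The deposited table holds 12460 genes (12180 protein-coding, 400 on the X chromosome, 1 on Y and 0 of the mitochondrial genome) and gives each library a raw and a normalized column. The raw columns hold expected counts per the file headers and the values themselves (10.1% whole numbers), with no scaling; they were rounded for the count models. The normalized columns, as deposited, hold log2 values that the authors centred on the median of the 8 Y-coded Input libraries of each gene, and were not tested. Per the file headers the authors kept genes with a raw value of at least 50 in all samples of at least 1 of 4 conditions; tested on the file, the conditions are age code by fraction, with 10498 genes passed in 4, so a gene present in 1 sex only could not be kept. The totals are sums over these genes and not sequencing depth. The build was mm10 and the authors' notes name DESeq; aligner, counting tool and their versions are not given in the sources used here. Coordinates are those of the table (Rpe65: chromosome 3, 159599181 to 159625307, plus strand). Counting of reads shared by near-identical genes is not described, so values of single haemoglobin, ribosomal protein and MHC genes, and of Gm20594, are uncertain. Best1 and mitochondrially encoded genes are not in the table used.

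Input and Positive of a pool came from 1 lysate. Checked on the counts, each of 15 Positive libraries correlated best with its own pool's Input in deviations from the fraction mean (0.427 to 0.751, median 0.607; -0.0627 with other pools). Among pairs of libraries of 1 code and fraction none were duplicates (lowest chi-square per degree of freedom 7.95). Other pairs were not compared in this way. The codes OF, OM, YF and YM stand in the table's header and are not spelled out; they were read as age and sex because the series title names both, and the X escape genes were higher under F. The comparisons of age and sex were added after the header was seen and before any test. Pools are numbered 1 to 15 in the order in which the series lists their samples. Within blocks B and D this is not the order of library numbers. By library number O-coded pools fill numbering blocks A (pools 1 to 3) and B (4 to 7), Y-coded pools C (8 to 11) and D (12 to 15).

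Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr with a minimum count of 10 (0 genes removed), robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. Positive against Input used 2 groups without a block; age, sex and their interactions used 1 fit with 8 means (code by fraction). Values are log2 fold changes ± SE, CPM uses TMM-scaled totals, and log2 CPM a prior count of 2. Gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01; adjusted over the lists), which compares a list with the other genes, with an estimated correlation and fry, which compares it with no change, as alternatives. Of 27 lists fixed before the files and 15 added before any test, 40 had at least 3 measured members and were tested over 16 contrasts. Lists of surface epithelium and adipocyte genes were written after high Krt23 and high Cfd, Car3 and Fabp4 had been seen. Of the lens crystallin list only Cryab is in the table (0.69 ± 0.138 within pools, SD, n = 15), so it was not tested as a list. Shares of counts were compared within pools by exact sign-flip tests over 32768 flips, adjusted over 7 measures (6.1e-05 becomes 8.54e-05).

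Named genes followed a rule. For Positive against Input: the 5 largest and 5 smallest changes among genes past the threshold, with the same sign in 15 pools and mean expression above the median; the 2 most expressed members of each fixed list (3 for the first lists); and Rpe65, Best1, Aldh1l1, Glul, Rho and Pecam1. For age the rule took the 8 largest and 8 smallest and for sex 5 and 5, above the median expression of the Positive fraction, and the 2 members of smallest p per list. Other members, named as exceptions or examples of a list, and the lists and genes in the plots were chosen after their values were seen.

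Models were tried on simulated data with 200 changed genes among 12460. Positive against Input with pools as a block recovered 29 of 50 genes at 1.25-fold, 42 at 1.5-fold, 48 at 2-fold and 50 at 4-fold (2.31% false calls). A second run of that model recovered 32, 41, 50 and 50 (4.95%). The fit without a block, which gave the main result, was not simulated. Age recovered 13, 31, 46 and 50 (6.04%) and sex 9, 30, 49 and 50 (4.17%), without simulated differences between pools. Alternatives were DESeq2's size factors and Wald test (1.42.0), upper-quartile scaling, limma-voom, no filter, a minimum count of 100, pools as a block, the block with a correction for gene length and GC (known for 96.7% of genes, GENCODE), each numbering block and each pool left out, numbering block as a covariate for sex, and Positive libraries alone. Leaving out pools 1, 2 and 5, which had the highest surface epithelium levels in Input, a pool block for sex by fraction, and for age by fraction a pool block with an estimated correlation, were chosen after results were seen.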

Results

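Eyecups of retinal pigmented epithelium (RPE) and choroid came from mice with a tamoxifen-inducible Cre under the Aldh1l1 promoter. Their NuTRAP reporter tags ribosomes of Cre-expressing cells with green fluorescent protein (GFP). Each of 15 pools held 4 eyecups of 2 mice and gave an Input library, of the whole lysate, and a Positive library, of RNA captured with an antibody against GFP. The pools, of different mice, are biological replicates, and every p below treats the pool or its library as the unit. Fits without a pool block treat the Input and Positive libraries of a pool as independent, although they share a lysate. The table's header gives each pool a code, taken here as age (O or Y) and sex (F or M): OF for 4 pools, OM for 3, YF for 4 and YM for 4. In units of 1e6 counts, the 12460 genes summed to 11.8 to 20.2 per Input library (mean 16.3 ± 2.32, SD, n = 15) and 11.7 to 21.7 per Positive library (16.5 ± 2.89, n = 15). The difference within pools, 0.192 ± 2.23, lay inside that spread (two-sided exact sign-flip test, p = 0.739).

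Which RNAs the tagged ribosomes carried was asked by comparing Positive with Input. RPE genes rose in the captured RNA. Rpe65, the isomerase of the visual cycle, rose by 0.82 ± 0.0723 (log2, ± SE, 15 against 15 libraries, 2628 ± 289 against 1494 ± 226 CPM, mean ± SD). Aldh1l1, the gene whose promoter drives the Cre, rose by 0.72 ± 0.0627 (97.4 ± 12.5 against 59.0 ± 6.56 CPM). Both were higher in 15 of 15 pools. Of 12 visual cycle genes 11 rose, among them Ttr (0.75 ± 0.0975), Rgr (0.64 ± 0.0627) and Rlbp1 (0.79 ± 0.0752), which carry or bind retinoids. The serum retinol carrier Rbp4 (0.53 ± 0.383, adjusted p = 0.213) was not past the threshold, and the list's median was 0.75 (adjusted p = 0.192 with an estimated correlation). Among 19 RPE identity and transport genes 17 rose, with Enpp2 0.77, the lactate transporter Slc16a8 0.74 and Mfrp 0.60 as examples. Only the secreted serpin Serpinf1 fell (-2.98), for a median of 0.60 (adjusted p = 0.459 with an estimated correlation). Glul, the glutamine synthetase gene, rose by 0.60 ± 0.0481. Visual cycle genes made up 2.89 ± 0.242% of Positive counts against 1.88 ± 0.239% of Input counts (SD, n = 15, two-sided exact sign-flip test, p = 6.1e-05, the smallest the test can give).

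Genes of the neighbouring vessels and stroma, and rod genes, fell in the captured RNA. All 14 endothelial genes fell (median -3.39, adjusted p = 0.00219 with an estimated correlation), with Pecam1 at -3.31 ± 0.171 (8.04 ± 3.65 against 80.3 ± 8.29 CPM) and Plvap at -3.44. So did all 9 mural cell genes (median -2.38, adjusted p = 0.027 with an estimated correlation), with Tagln at -3.24 and Pdgfrb at -2.92. Of 12 fibroblast and scleral genes 11 fell (median -3.03, adjusted p = 0.000121 with an estimated correlation), with Dcn at -2.98 and Col1a2 at -2.90, and Fbln1 alone rose (0.26). Among 15 rod genes 14 fell (median -3.23, adjusted p = 0.143 with an estimated correlation), the visual pigment Rho by 3.58 ± 0.168 (27.3 ± 8.20 against 327 ± 103 CPM). The outer segment gene Rom1 rose (0.88 ± 0.0808, a mean of 372 against 203 CPM). It held much of the rod counts in Positive libraries, so the summed rod share fell less than most rod genes did. Rod genes made up 0.0435 ± 0.00408% of Positive and 0.103 ± 0.0256% of Input counts, and haemoglobin genes 0.00834 ± 0.00957% and 0.108 ± 0.0817% (both n = 15, two-sided exact sign-flip test, p = 6.1e-05). All 5 erythrocyte genes fell (median -3.67, adjusted p = 0.484 with an estimated correlation), with Hba-a1 at -3.44 and Beta-s at -3.67. Reads shared by near-identical haemoglobin genes leave each single value uncertain, and the list's call was also lost without numbering block D (adjusted p = 0.0585). Of 8 retinal interneuron genes 5 fell, including Calb2 (-4.04), Snap25 (-3.36) and Nefl (-3.26), and 2 rose, Vsx2 (0.82) and the glycine transporter Slc6a9 (0.69). The call on this list (median -0.44) was lost with pools as a block (adjusted p = 0.150), with the block and a length and GC correction, with limma-voom, with the stricter filter and with an estimated correlation (adjusted p = 0.156). Its adjusted p ran from 0.0162 to 0.413 over the camera alternatives.

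Energy genes rose and several RNA classes fell. All 20 nuclear-encoded respiratory chain genes rose (median 0.69, adjusted p = 0.213 with an estimated correlation), with Atp5b at 0.58 ± 0.0431 and Atp5a1 at 0.63 ± 0.0470. All 15 genes of fatty acid oxidation and ketogenesis rose (median 0.52, adjusted p = 0.0945 with an estimated correlation), the ketone-forming Hmgcs2 by 0.71 and Acox1 by 0.60. So did all 12 glycolysis genes (median 0.53, adjusted p = 0.00922 with an estimated correlation), with Ldhb at 0.69 and Pgk1 at 0.63. Of 11 oxidative stress genes 7 rose and 0 fell (median 0.33, adjusted p = 0.0945 with an estimated correlation), including Sod2 (0.73), Cat (0.68) and Sod1 (0.61). Skeletal muscle genes rose as well, 9 of 10 (median 1.04, adjusted p = 0.579 with an estimated correlation), with Tnnc2 at 1.40 and Tnni2 at 1.28. They made up 1.86 ± 0.534% of Positive against 1.03 ± 0.293% of Input counts. Transcripts that stay in the nucleus fell, 6 of 7 long noncoding RNAs (median -1.92, adjusted p = 0.156 with an estimated correlation), with Neat1 at -1.68 and Malat1 at -1.72. Of 22 cytosolic ribosomal protein genes 20 fell (median -0.73, adjusted p = 0.51 with an estimated correlation), with Rps2 at -1.18 and Rpl4 at -0.68.

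Lists of matrix, complement and secretory genes moved down. Of 11 complement genes 8 fell and 2 rose (median -0.98, adjusted p = 0.017 with an estimated correlation). C1s (-3.15), C1ra (-2.65), C3 (-2.50) and Serping1 (-2.27) were lowest. Cfd (1.24) and Cd59a (0.32) rose, and the regulator Cfh (-0.07 ± 0.108) was not past the threshold. Of 11 basement membrane genes 7 fell, including Nid1 (-2.74) and Col4a1 (-2.02), and 2 rose, Col18a1 (0.48) and Timp3 (0.36), for a median of -0.84 (adjusted p = 0.197 with an estimated correlation). Of 7 senescence and secretory genes 5 fell, Igfbp3 the most (-3.84), and Serpine1 rose (0.63), for a median of -1.03 (adjusted p = 0.156 with an estimated correlation). The ciliary body list split, with Myoc (-4.37), Tfap2b (-3.03) and the water channel Aqp1 (-2.87) lower and Cldn2 (0.72), Zic1 (0.90) and Wls (0.28) higher among 8 genes. The mean was -1.05 but the median near 0, and the call was lost with an estimated correlation (adjusted p = 0.156) and with limma-voom (adjusted p = 0.415).

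Of 40 lists 21 were not past the threshold as lists, although single members changed. Of 10 melanin synthesis genes 4 rose and 0 fell (median 0.38, adjusted p = 0.165). Dct (0.25 ± 0.135, adjusted p = 0.0948) passed with pools as a block (adjusted p = 0.00269), with the block and a length and GC correction, and with DESeq2's Wald test, over a range of 0.000455 to 0.264 in the alternatives. Of 6 melanocyte genes 2 rose, with Sox10 at 0.56, and 1 fell (median -0.09, adjusted p = 0.74). Ednrb (-0.19 ± 0.248, adjusted p = 0.502) passed only with the block (adjusted p = 0.0139), over a range of 0.0139 to 0.658. Macrophage and microglia genes split within 13, with Csf1r (0.63) and Tyrobp higher and Cx3cr1, Ptprc, Emr1 and Mrc1 lower (median -0.20, adjusted p = 0.74). Müller glia had 8 of 12 higher and 4 lower (median 0.44, adjusted p = 0.165), with Clu at 0.50. The astrocyte list had 4 of 7 higher, S100b by 0.83 and Gja1 by 0.39, and Gfap lower (-2.04, list median 0.39, adjusted p = 0.165). Of 18 lysosome genes 10 rose and 3 fell (median 0.19, adjusted p = 0.149, Psap 0.42, Ctsd 0.51). Among 10 phagocytosis genes 1 rose and 3 fell (median -0.09, adjusted p = 0.99, Gas6 -0.14, Rac1 -0.20). The call on Gas6 was lost with DESeq2's size factors and without numbering block C or D (adjusted p up to 0.0855). Among 11 cell junction genes 5 rose, Cdh3 by 0.61, and 2 fell (median 0.03, adjusted p = 0.536). All 4 MHC class II genes fell (median -0.93, adjusted p = 0.0506). This list was called with upper-quartile scaling, limma-voom, the stricter filter, and without numbering block A or B (adjusted p from 0.0226 to 0.51 over 12 camera alternatives). So did 8 of 9 MHC class I genes (median -0.75, adjusted p = 0.0842), a list called with the block (adjusted p = 0.0328), with the block and a length and GC correction and with limma-voom (from 0.00569 to 0.579). The fry test asks whether a list's genes moved, on balance, in 1 direction, not whether they moved more than other genes, and called 34 of the 40 lists.

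Of the other lists only surface epithelium was past the threshold with the preset correlation. Of 6 Schwann cell genes 4 fell, Mpz by 4.60 and Mbp by 0.33 (median -0.38, adjusted p = 0.231). Of 5 cone genes 2 rose, Gnat2 by 0.35, and 2 fell (median -0.20, adjusted p = 0.74). Of 9 iron genes 4 rose, transferrin (Trf) by 0.63, and 3 fell, the ferritin Ftl1 by 1.83 (median 0.12, adjusted p = 0.714). Of 12 cholesterol and lipid genes 2 rose and 5 fell (median -0.09, adjusted p = 0.732). Among 11 clock genes 5 rose and 4 fell (median 0.03, adjusted p = 0.263), and among 9 unfolded protein response genes 1 rose and 5 fell (median -0.20, adjusted p = 0.66). The numbers were 1 and 4 of 8 acute phase genes (median -0.46, adjusted p = 0.698), 1 and 6 of 10 interferon-stimulated genes (median -0.39, adjusted p = 0.714) and 0 and 4 of 7 cell cycle genes (median -0.45, adjusted p = 0.546). In the lymphocyte and mast cell list 2 of 6 rose and 2 fell (median 0.41, adjusted p = 0.99). Of 5 genes that escape X inactivation 0 rose and 2 fell (median 0.03, adjusted p = 0.99). A list of surface epithelium genes written after the sex results were seen fell in 16 of 19 (median -2.66, adjusted p = 0.679 with an estimated correlation). An adipocyte list written after the age results were seen had 3 of 8 higher and 1 lower (median 0.62, adjusted p = 0.689).

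Over all genes 4369 rose and 4701 fell in the captured RNA out of 12460 (edgeR's quasi-likelihood test, Benjamini-Hochberg), 212 and 1585 of them at least 2-fold. Among well-expressed genes with the same sign in every pool the largest rises were of Lars2, the mitochondrial leucyl-tRNA synthetase (2.23 ± 0.194, a mean of 368 against 78.3 CPM), and the muscle genes Dhrs7c (1.69 ± 0.216) and Cox6a2 (1.65 ± 0.179). Next came Rangap1, an activator of the Ran GTPase (1.63 ± 0.271), and the potassium channel gene Kcna7 (1.63 ± 0.202). Within pools the rise of Lars2 varied most (SD 0.680), against 0.154 for Dhrs7c, 0.246 for Cox6a2, 0.322 for Rangap1 and 0.216 for Kcna7. Whether all reads counted for Lars2 came from its own RNA was not tested. The largest falls were of the endothelial mucin Emcn (-4.55 ± 0.158, 5.75 ± 2.15 against 135 ± 25.7 CPM), Myoc (-4.37 ± 0.229), Gm20594 (-4.35 ± 0.129), the methyltransferase gene Inmt (-3.99 ± 0.166) and the pericyte gene Rgs5 (-3.88 ± 0.288). The 10 most abundant genes held 6.53 ± 0.271% of Positive and 5.12 ± 0.332% of Input counts. In the 4 blocks of consecutive library numbers 98.8%, 99.8%, 99.3% and 99.2% of the called genes kept their sign. The calls were made on all libraries, those of each block included, so this is no independent check. Macrophage genes turned with the block (medians 0.36, 0.03, -0.73 and -0.70 in blocks A to D). These values are shares of each library, so they do not tell a gain in 1 RNA from a loss of others.

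**Figure D1:**
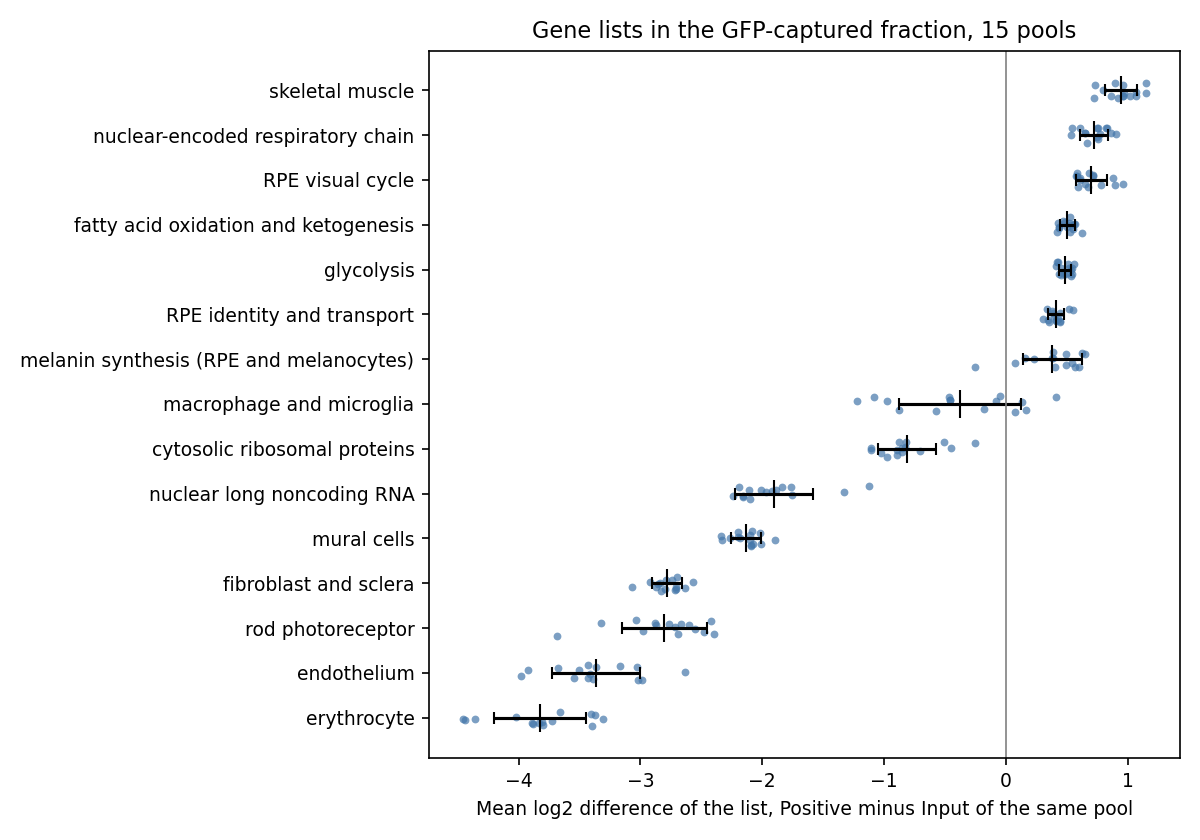
Mean log2 difference, Positive minus Input of the same pool, for 15 gene lists picked after their values were seen, with a dot for each of 15 pools and the mean ± SD in black. Endothelial, rod, fibroblast and erythrocyte lists lie below 0 in every pool, and muscle, respiratory chain and visual cycle lists above 0.

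Whether the captured RNA differed with age was asked by comparing 7 O-coded with 8 Y-coded pools. Genes of macrophages rose in O-coded pools, 12 of 13 in the Positive fraction (median 1.06, adjusted p = 0.00474 with an estimated correlation). Cd68 rose by 1.38 ± 0.126 (111 ± 34.1 against 45.6 ± 17.4 CPM, mean ± SD), the complement gene C1qc by 1.24 ± 0.114 (203 ± 47.5 against 89.4 ± 23.8 CPM) and Tyrobp by 1.46 ± 0.163, while Csf1r (0.33 ± 0.140) was not past the threshold. Of 10 phagocytosis genes 5 rose (median 0.22, adjusted p = 0.00474 with an estimated correlation), led by the bridging protein gene Mfge8 (1.70 ± 0.124, a mean of 514 against 162 CPM), Lgals3 (1.19) and Cd36 (0.97). Mast cell and lymphocyte genes rose in 4 of 6 (median 1.04, adjusted p = 0.00931 with an estimated correlation), among them the mast cell protease Cpa3 (1.24 ± 0.127, 23.9 ± 4.02 against 10.1 ± 2.35 CPM). All 10 melanin synthesis genes fell (median -0.86, adjusted p = 0.00393 with an estimated correlation). The transporter Slc45a2 fell by 1.46 ± 0.121 (95.8 ± 30.3 against 254 ± 25.6 CPM). Also lower were the melanosome matrix gene Pmel (-1.45 ± 0.159), the regulator Mitf (-0.90 ± 0.0909) and tyrosinase (Tyr, -0.61 ± 0.0875). Melanocyte genes fell in 4 of 6 (median -0.95, adjusted p = 0.00474 with an estimated correlation), with Ednrb at -1.58 ± 0.113 (93.8 ± 23.6 against 274 ± 23.2 CPM), Mc1r at -1.15 and Kit at -0.82.

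**Figure D2:**
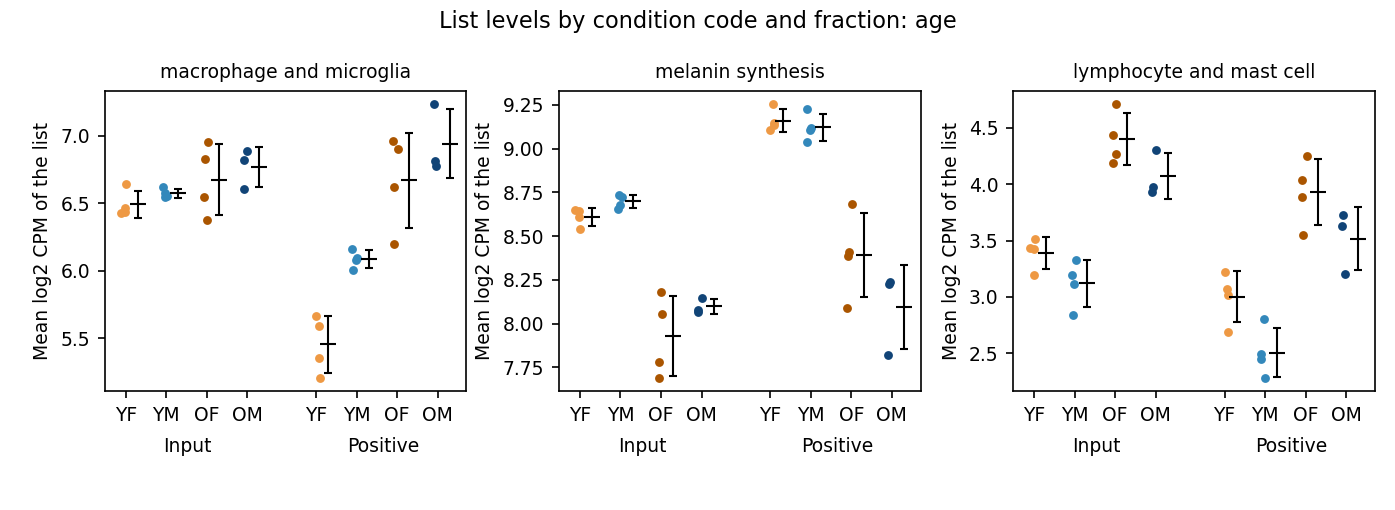
Mean log2 CPM of the macrophage, melanin synthesis and lymphocyte and mast cell lists, picked after their values were seen, per library (dots) by header code and fraction, with mean ± SD beside them (3 or 4 pools each). Macrophage levels part the O and Y codes in the Positive libraries, with medians over genes of 1.06 there and 0.18 in Input.

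Further lists changed with age in the Positive fraction, most of them only with the preset correlation. Of 8 acute phase genes 4 rose (median 0.47, adjusted p = 0.373 with an estimated correlation): C3 (2.13), Lcn2 (1.92), Stat3 (0.48) and A2m (0.46). Of 5 cone genes 3 rose, Gngt2 (1.44), Gnb3 (1.20) and Gnat2 (0.34), for a median of 0.34 (adjusted p = 0.0881 with an estimated correlation). This call was lost with upper-quartile scaling (adjusted p = 0.055) and limma-voom (adjusted p = 0.0531), and the adjusted p ran from 0.00459 to 0.055 over the alternatives with the preset correlation. Fibroblast genes fell in 6 of 12, with Col1a1 at -1.15 ± 0.132 and Col1a2 at -0.82, while Dpt rose (1.10), for a median of -0.32 (adjusted p = 0.0881 with an estimated correlation). Among 22 ribosomal protein genes 7 fell (median -0.29, adjusted p = 0.782 with an estimated correlation). The astrocyte list had 2 of 7 lower, S100b at -1.32 among them (median -0.20, adjusted p = 0.0387 with an estimated correlation). In the lists written after results were seen 7 of 8 adipocyte genes rose, among them Cfd, Car3 and Fabp4, whose rise led to the list. Without these, 4 of 5 rose (median 1.00, adjusted p = 0.000263, and 0.105 with an estimated correlation). So did 7 of 19 surface epithelium genes (median 0.66, adjusted p = 0.739 with an estimated correlation), and the latter call was lost with limma-voom and without pools 1, 2 and 5 (median 0.08, adjusted p = 0.62, from 0.0106 over the alternatives with the preset correlation). Of the rod, respiratory chain, fatty acid oxidation, muscle and erythrocyte genes 0 were past the threshold for age.

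Neither the visual cycle nor the RPE identity list was past the threshold for age. Of 12 visual cycle genes Rbp4 rose (2.33) and 2 fell, Ttr by 0.37 among them (median -0.14, adjusted p = 0.574). The call on Ttr was lost without pools 1, 2 and 5 (adjusted p = 0.068, from 0.000828 over the alternatives). Of 19 RPE identity genes only Serpinf1 fell (-0.90, median 0.01). Cell junction genes included Cdh1, which encodes E-cadherin (-1.48 ± 0.161, 56.3 ± 24.6 against 148 ± 14.8 CPM), and Ctnnb1 (-0.38), and 0 of 11 rose. Of 14 endothelial genes 2 fell (median -0.14, adjusted p = 0.3). Of 9 MHC class I genes 3 rose, Psmb8 by 0.93 (median 0.36, adjusted p = 0.0702). Of 18 lysosome genes 6 rose, Hexb by 0.72 and Ctsb by 0.45, and 1 fell (median 0.08, adjusted p = 0.138). The oxidative stress gene Hmox1 rose by 0.54 and the clock gene Per2 by 0.67.

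Over all genes 1356 rose and 1261 fell in O-coded Positive libraries (7 against 8 libraries, edgeR's quasi-likelihood test), 380 and 108 at least 2-fold. A fit of the Positive libraries alone gave 1036 higher and 849 lower. Among well-expressed genes the largest rises were of haptoglobin (Hp, 3.28 ± 0.462, 56.5 ± 40.0 against 8.53 ± 7.81 CPM), the carbonic anhydrase gene Car3 (2.78 ± 0.410), the complement protease gene Cfd (2.47 ± 0.467), Ifi27l2a, induced by interferon (2.24 ± 0.296, 116 ± 59.3 against 24.8 ± 6.29 CPM) and Nnat (2.23 ± 0.367). The chemokine gene Ccl6 (2.07 ± 0.224, 56.7 ± 29.0 against 12.6 ± 3.72 CPM), the lipid carrier Fabp4 (2.06 ± 0.307) and Cbr2 (2.04 ± 0.301) followed. The largest falls were of Stmn3, which acts on microtubules (-2.28 ± 0.211, 18.2 ± 8.62 against 83.2 ± 22.9 CPM), the DNA repair gene Brca1 (-2.07 ± 0.245, 48.2 ± 25.0 against 196 ± 27.8 CPM) and Prb1 (-1.85). The synuclein gene Snca (-1.80 ± 0.171, 17.2 ± 7.18 against 55.4 ± 8.42 CPM), Car6 (-1.78 ± 0.176), the connexin gene Gjb6 (-1.70), Ednrb and the glycine receptor gene Glrb (-1.57 ± 0.164) followed. Without pools 1, 2 and 5, which leaves OF a lone pool assumed to vary like the other groups, 513 rose, 150 of them at least 2-fold, and 603 fell. All O-coded pools lie in numbering blocks A and B and all Y-coded pools in C and D, so age cannot be told apart from these blocks. In the Positive fraction 1806 genes differed between C and D, within the Y code, and 1 between A and B.

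**Figure D3:**
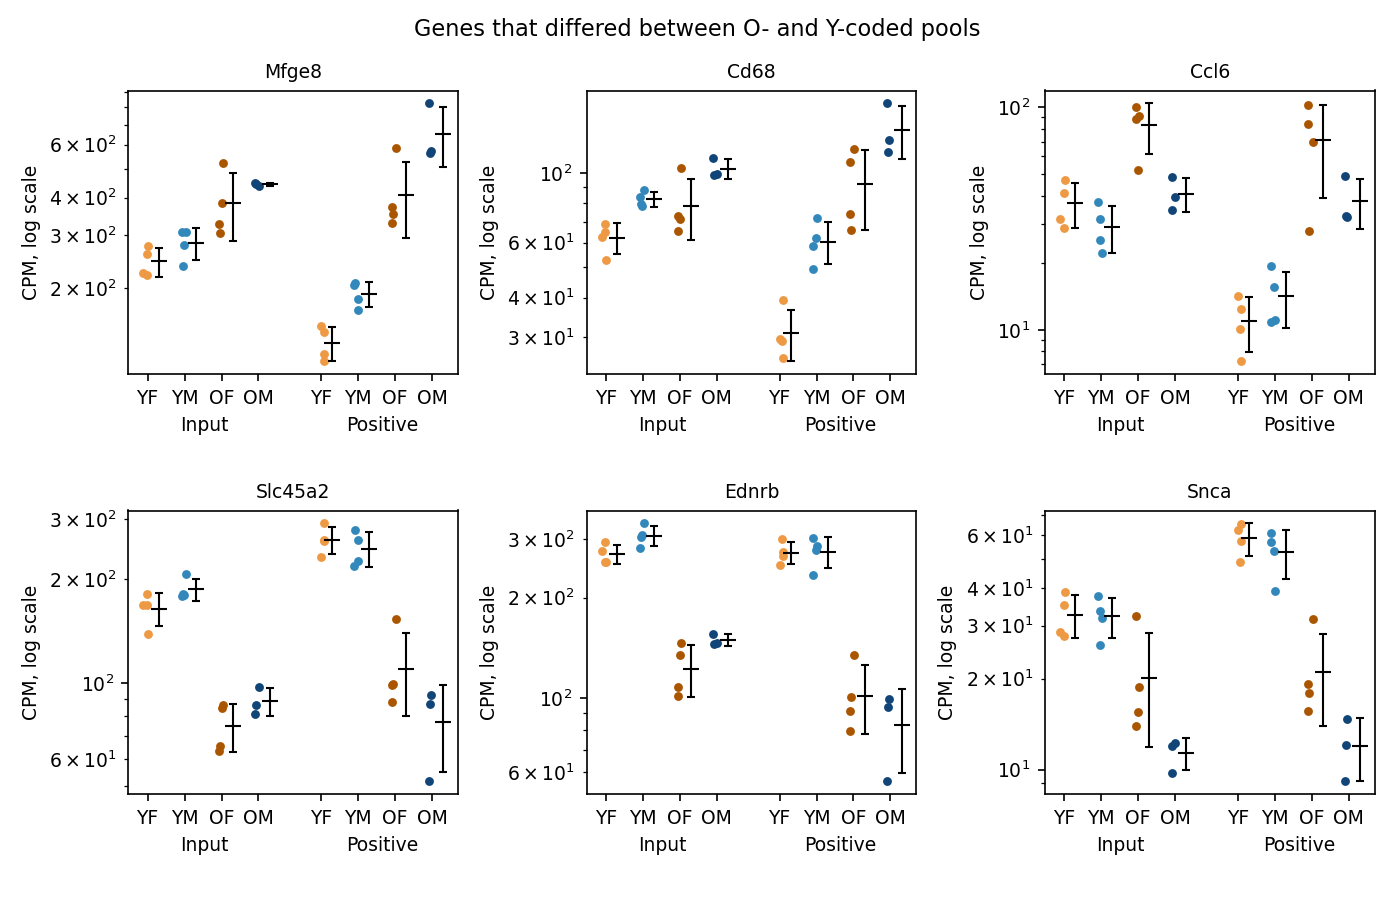
CPM (log axis) of Mfge8, Cd68, Ccl6, Slc45a2, Ednrb and Snca, picked after their values were seen, per library (dots) by header code and fraction, with mean ± SD beside them (3 or 4 pools each). Cd68 lies at 111 ± 34.1 CPM in O-coded and 45.6 ± 17.4 CPM in Y-coded Positive libraries.

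In Input 1075 genes rose and 1167 fell in O-coded pools (7 against 8 libraries). Melanin synthesis genes fell there too, 9 of 10 (median -0.62, adjusted p = 0.0136 with an estimated correlation), with Slc45a2 at -1.11. All 6 lymphocyte and mast cell genes rose (median 0.87, adjusted p = 0.0123 with an estimated correlation). Acute phase genes rose in 6 of 8 (median 0.56, adjusted p = 0.252 with an estimated correlation) and complement genes in 4 of 11 (median 0.20, adjusted p = 0.0841 with an estimated correlation). Schwann cell genes fell in 4 of 6 (median -0.45, adjusted p = 0.0894 with an estimated correlation), and melanocyte genes in 4 of 6 with 1 higher, Erbb3 (median -0.51, adjusted p = 0.149 with an estimated correlation). Fibroblast genes fell in 6 of 12 (median -0.28, adjusted p = 0.239 with an estimated correlation), a call lost with limma-voom (adjusted p = 0.0582, from 0.00161 over the alternatives with the preset correlation). Macrophage genes passed in 2 of 13 (median 0.18), and the list was not past the threshold (adjusted p = 0.0598). The counts moved by over 1.5 times without pools 1 (714 higher), 3 (645 higher, 769 lower) and 7 (649 higher, 691 lower), and without pools 1, 2 and 5 together to 98 and 212.

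Whether age acted differently on the captured RNA than on the whole lysate was tested as a difference of differences. The age difference of macrophage genes was larger in the Positive fraction for 9 of 13 (median 0.92, adjusted p = 0.00435 with an estimated correlation). Cd68 by 1.05 (adjusted p = 0.00123), C1qc by 1.03 (adjusted p = 0.000752), Tyrobp by 1.07 and Mrc1 by 1.07 were among them. Phagocytosis genes followed for 3 of 10, Mfge8 by 1.05 (adjusted p = 0.00109), Cd36 by 0.92 and Itgb5 by 0.33 (median 0.16, adjusted p = 0.00667 with an estimated correlation). Iron genes went the same way for 2 of 9, the ferritins Fth1 (0.52) and Ftl1 (0.54). This list's call was lost with DESeq2's size factors (adjusted p = 0.0509), without pools 1, 2 and 5 (adjusted p = 0.316, from 0.00828 over the alternatives with the preset correlation) and with an estimated correlation (adjusted p = 0.117). Kit fell more in the Positive fraction (-0.76, adjusted p = 0.0065), as did Cdh1 (-1.17, adjusted p = 0.00321). In 6 other called lists at most 1 gene passed, and each call was lost with an estimated correlation. They were lysosome (Ctsb 0.35, list median 0.14, adjusted p = 0.276), MHC class II (0.50, adjusted p = 0.276) and melanin synthesis genes (-0.22, adjusted p = 0.286). The others were melanocyte (Kit, list median -0.45, adjusted p = 0.0953), cell junction (Cdh1, list median -0.16, adjusted p = 0.276) and ribosomal protein genes (-0.21, adjusted p = 0.675), all with an estimated correlation. The cell junction call was also lost without pools 1, 2 and 5 (adjusted p = 0.0701, from 0.000395 over the alternatives with the preset correlation).

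In all 202 genes had a higher and 65 a lower age difference in the Positive fraction than in Input (7 against 8 pools). With pools as a block these became 574 and 352. The fibroblast (-0.18, adjusted p = 0.0132), MHC class I (0.01, adjusted p = 0.0143), visual cycle (0.08, adjusted p = 0.0381), rod (0.29, adjusted p = 0.0365) and adipocyte (0.24, adjusted p = 0.00314) lists gained a call, and with the block and an estimated correlation none of these was past the threshold (adjusted p = 0.31, 0.346, 0.637, 0.662 and 0.333). The counts moved by over 1.5 times without pool 3 (105 and 28), pool 8 (126 higher), pool 10 (126 and 42), pool 7 (40 lower) or pool 13 (41 lower), and were 52 and 25 without pools 1, 2 and 5. DESeq2 gave 117 lower.

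Whether age acted differently in F-coded and M-coded pools was tested as an interaction. In the Positive fraction 0 genes passed (edgeR, 628 at unadjusted p below 0.05, smallest adjusted p = 0.782, 1 gene with DESeq2 and 0 with limma-voom). In Input 0 passed (696 at unadjusted p below 0.05, 1 with DESeq2 and 0 with limma-voom). Taken by sex, 1353 genes changed with the O code among F-coded pools (4 against 4), 820 of them upward, and 423 rose and 482 fell among M-coded pools (3 against 4). Upward 313 and downward 288 were shared, where independent lists would share 27.8 and 20.6. The log2 differences of the sexes had r = 0.677 across genes, which are not independent of each other. Of 40 lists 7 were called for the interaction with the preset correlation, each with a higher O minus Y value in F-coded pools and each lost with an estimated correlation. They were macrophage (median 0.36, adjusted p = 0.647), Schwann cell (adjusted p = 0.299), melanin synthesis and acute phase (adjusted p = 0.697 each), erythrocyte (adjusted p = 0.697), ribosomal protein (adjusted p = 0.911) and senescence genes (adjusted p = 0.647). The surface epithelium list, written later, was called as well (median 1.77, adjusted p = 0.343 with an estimated correlation), as was RPE identity in Input (median -0.17, adjusted p = 0.853 with an estimated correlation).

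Sex differences in the captured RNA were asked with 8 F-coded against 7 M-coded pools. Genes that escape X inactivation rose in F-coded pools, 3 of 5. Their higher level under F was also a ground for reading the codes as sex, so it is no separate support for that reading. Eif2s3x, a translation factor gene, rose by 0.65 ± 0.0501, Kdm6a by 0.79 ± 0.0781 and Ddx3x by 0.44 (median 0.44, adjusted p = 3.19e-06 with an estimated correlation). Endothelial genes fell in 12 of 14 (median -0.73, adjusted p = 0.021 with an estimated correlation). The receptor gene Tie1 was at -1.05 ± 0.134 (5.12 ± 1.18 against 10.6 ± 1.94 CPM) and Pecam1 at -1.04 ± 0.151 (5.45 ± 1.83 against 11.0 ± 2.83 CPM). This difference exceeded that of Input, where the list's median was -0.14, by a median of -0.53 (adjusted p = 0.0379 with an estimated correlation). Singly, 0 of 14 genes passed over all genes and 9 adjusted over the list alone. Endothelial RNA was depleted in Positive libraries (Pecam1 at a mean of 8.04 CPM against 80.3 in Input, over all pools). Whether the sex difference lies in tagged cells or in endothelial RNA left over from the lysate was not tested. Macrophage genes fell in 6 of 13 (median -0.45, adjusted p = 0.142 with an estimated correlation), with Cd68 at -0.78 and Emr1 at -0.75. Of 10 phagocytosis genes 2 fell, Mfge8 (-0.61) and Cd36 (-0.64, lost with the Positive libraries alone, adjusted p = 0.0767, from 0.0044 over the alternatives, list median -0.15, adjusted p = 0.0941 with an estimated correlation), and the list's call was lost without pools 1, 2 and 5 (adjusted p = 0.0594, from 0.0246 with the preset correlation). Surface epithelium genes, in the list written after these results, rose in 8 of 19 (median 1.21, adjusted p = 0.168 with an estimated correlation), Aqp5 by 2.26 and Krt23 by 0.66. Without Krt23, whose level led to the list, 7 of 18 rose (adjusted p = 0.207 with an estimated correlation). The call on Aqp5 was lost with limma-voom and without pools 1, 2 and 5 (value down to 1.60, adjusted p up to 0.183).

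**Figure D4:**
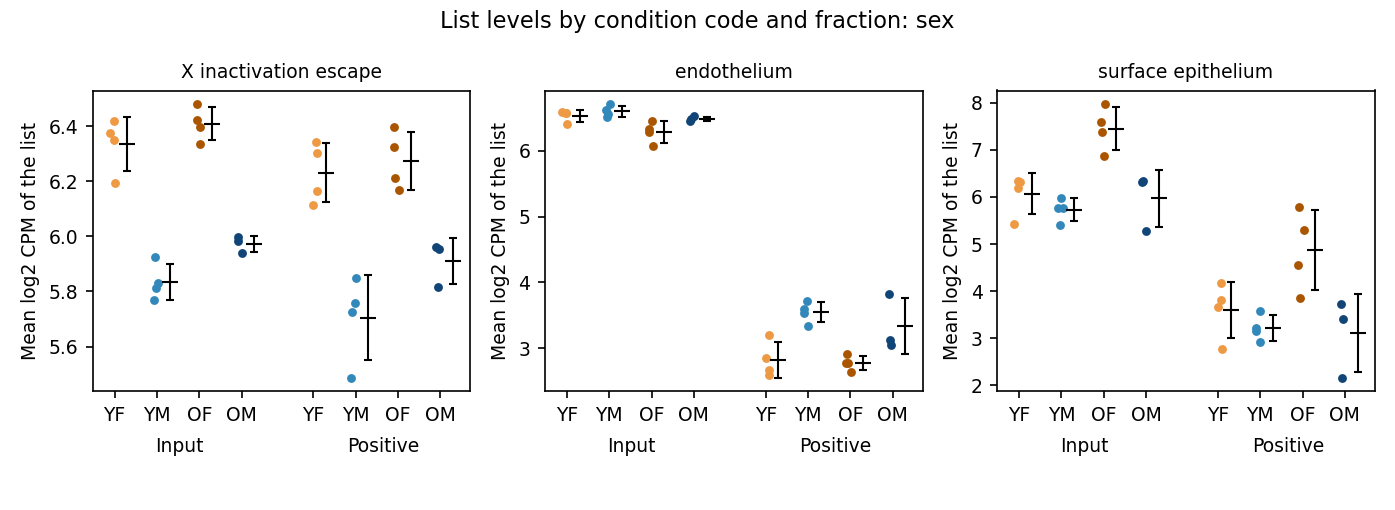
Mean log2 CPM of the X inactivation escape, endothelium and surface epithelium lists, picked after their values were seen, per library (dots) by header code and fraction, with mean ± SD beside them (3 or 4 pools each). The X escape list lies higher in F than in M codes in both fractions, with medians of 0.44 (Positive) and 0.39 (Input).

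The other called lists rested on few genes. Melanin synthesis had 1 of 10 higher, Dct (0.45, median 0.13, adjusted p = 0.645 with an estimated correlation), a call lost with the Positive libraries alone (adjusted p = 0.0644, from 0.00359 over the alternatives with the preset correlation). The lymphocyte and mast cell list had 1 of 6, Cma1 (0.56, adjusted p = 0.23 with an estimated correlation), a list call lost without pools 1, 2 and 5 (adjusted p = 0.189, from 0.00332 with the preset correlation). Cma1 itself was lost there and with the Positive libraries alone (adjusted p up to 0.215). Complement had 3 of 11 higher, with C1s at 0.43 and C4b at 0.40 (median 0.26, adjusted p = 0.23 with an estimated correlation). Without pools 1, 2 and 5 its median turned to -0.147, and the adjusted p ran from 0.0376 to 0.885 over the alternatives with the preset correlation, with the call also lost with the Positive libraries alone, limma-voom and the numbering block. C4b lost its call with the Positive libraries alone and without pools 1, 2 and 5 (value down to 0.18, adjusted p up to 0.285). Among genes with above-median expression in Positive libraries the largest rises were of Pglyrp1, a bacterial wall receptor gene (2.08 ± 0.446), the serpin gene Serpine3 (1.70 ± 0.286, 373 ± 152 against 121 ± 62.7 CPM), and the epidermal genes Asprv1 (1.49 ± 0.342), Krt5 (1.41 ± 0.393, 122 ± 131 against 39.2 ± 23.6 CPM) and Calml3 (1.33 ± 0.319). The largest falls at that expression were of Hp (-1.91 ± 0.454), the fungal receptor gene Clec7a (-1.01 ± 0.133, 23.8 ± 9.84 against 45.4 ± 17.5 CPM), Atp6v0d2 (-0.99 ± 0.147), the glycogen regulator Ppp1r3c (-0.91 ± 0.259) and Mpeg1 (-0.90 ± 0.124). Without pools 1, 2 and 5, and so with a lone OF pool assumed to vary like the others, Pglyrp1 (1.36, adjusted p = 0.165), Asprv1 (1.18, adjusted p = 0.132), Krt5 (0.43, adjusted p = 0.597), Calml3 (0.61, adjusted p = 0.383) and Ppp1r3c (-0.93, adjusted p = 0.132) lost their calls. With the Positive libraries alone the adjusted p of Asprv1 (0.0619), Krt5 (0.152), Calml3 (0.091) and Ppp1r3c (0.102) missed the threshold, as did with limma-voom that of Hp (0.117), Pglyrp1 (0.0825), Krt5 (0.0804) and Calml3 (0.0583), and with DESeq2's size factors that of Ppp1r3c (0.0551).

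In all 456 genes differed in Positive libraries by sex (8 against 7 libraries, edgeR), 275 of them lower in F-coded pools. The higher count moved by over 1.5 times without pool 1 (551), 2 (97), 3 (98), 4 (99), 5 (104), 7 (77), 11 (111), 12 (298), 13 (93) or 14 (89). The lower count became 721 without pool 1 and 125 without pool 3, and 65.8%, 63.3% and 59.6% of its size without pools 2, 7 and 13. Positive libraries alone gave 48 higher and 78 lower, DESeq2 424 and 421, limma-voom 96 higher, the numbering block as a covariate 591 and 801, and the data without pools 1, 2 and 5 81 and 321. In Input 387 rose and 155 fell. X escape genes rose in 4 of 5 (median 0.39, adjusted p = 2.71e-06 with an estimated correlation). So did 3 of 7 cell cycle genes, Mki67 (1.15), Top2a (1.15) and Cdk1 (0.60, list median 0.60, adjusted p = 0.0306 with an estimated correlation), a call lost without pools 1, 2 and 5 (adjusted p = 0.0601, from 0.000961 over the alternatives with the preset correlation). Mural cell genes fell there in 2 of 9, Rgs5 (-1.15) and Pdgfrb (-0.29, list median -0.29, adjusted p = 0.0306 with an estimated correlation). Basement membrane genes fell in 2 of 11 (median -0.22, adjusted p = 0.767 with an estimated correlation), a call lost without the same pools (adjusted p = 0.0601, from 0.00703 with the preset correlation). The ribosomal protein list was called with 0 of 22 genes past the threshold (median 0.30, adjusted p = 0.767 with an estimated correlation). Of 6 lymphocyte and mast cell genes 2 rose (median 0.48, adjusted p = 0.557 with an estimated correlation), a call lost with limma-voom, with the numbering block and without those pools (adjusted p up to 0.0627). The higher count in Input moved by over 1.5 times without pool 1 (634), 2 (209), 3 (222), 4 (134), 5 (214), 6 (601), 8 (202), 11 (208), 13 (202) or 14 (191), and to 46.0% without pool 7. The lower count moved without pool 1 (350), 2 (56), 3 (61), 4 (50), 5 (91), 7 (50), 10 (92), 11 (72), 12 (281), 13 (51) or 14 (61). Without pools 1, 2 and 5 together the counts were 15 and 6, with DESeq2 590 and 294, with the numbering block as a covariate 910 and 616, and with limma-voom 260 lower. The sex difference of Positive and Input libraries differed for 0 genes (edgeR, 670 at unadjusted p below 0.05, smallest adjusted p = 0.0761, 6 higher and 16 lower with DESeq2, 0 with limma-voom). With pools as a block it differed for 84 higher and 241 lower. Of 40 lists 11 were called with the preset correlation and 1, endothelium, with an estimated correlation.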

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

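Of the tests in this part, those on muscle (except the length and GC correction), macrophage and melanin synthesis genes were chosen after the results were seen. In 4 or more pools of 1 code and fraction a single pool lay far from the rest in 8 of 117 groups, where chance gives about 1 in 20. Haemoglobin genes made up 0.394% of counts in Input of OF pool 1 (others 0.0691 to 0.110%) and 0.0418% in its Positive library (0.00392 to 0.00974%), and muscle genes 0.589% in Input of YM pool 11 (1.20 to 1.29%). The Positive library of YM pool 12 held 11.7 units of 1e6 counts (16.3 to 16.5). In Positive libraries the CPM of Car3 was 49.6 in YM pool 10 (27.0 to 30.7), of Car6 56.3 in OF pool 5 (26.3 to 30.6), of Krt5 88.0 in YM pool 13 (27.5 to 32.0) and of Calml3 11.0 in YM pool 11 (22.5 to 23.8).

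The age difference was larger in the Positive fraction than in Input, by the test of the difference itself, for Ccl6 (1.24), Clec7a (1.10), Atp6v0d2 (1.16) and Mpeg1 (0.937), for the macrophage list (median 0.918), and for 202 genes upward and 65 downward.

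Within the Y code 1806 genes differed between numbering blocks C and D in the Positive fraction, so how much of the age result is a batch could not be told. Codes were redrawn to see how many genes other groupings of the same libraries call. Positive against Input called 9070 genes, the most of 100 splits (highest other 2243, and 5623 when every pool was parted). Age in the Positive fraction called 2617 (highest other 1737), age in Input 2242 (1164), age by fraction 267 (22), sex in the Positive fraction 456 (47) and sex in Input 542 (444), each the most of 100. Among F-coded pools age called 1353, the most of 35 splits (389), but among M-coded pools 905, and 1 other of 35 splits called 963, so chance was not excluded there. The interaction of age and sex called 0 genes where a redrawn code called up to 1962. Such codes also mix the age groups, so these draws cannot show what chance alone would call for the interaction.

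Muscle genes rose in the captured RNA, although the Cre was driven by the Aldh1l1 promoter. Gene length and GC were not the whole cause, since the median was 0.737 with both corrected, down from 1.04, which leaves a part to them open. Without that correction muscle genes rose more than visual cycle genes in 14 of 15 pools (0.950 ± 0.132 against 0.702 ± 0.127). If RNA of visual cycle genes was kept in full, scaling alone after loss of other cells does not account for all of the rise. Where part of that RNA was lost too, visual cycle genes understate the effect of scaling and the test cannot decide. Whether scaling together with length and GC accounts for the rise was not tested. Muscle left on the eyecups remains open, since its test decides nothing. The Positive level followed that of its own Input (r = 0.964), and 4 of 41 other lists had a higher r. But 33 of these 41 had r of at least 0.5 (median of the 41 lists 0.763), as both libraries came from 1 lysate. Why the capture exceeded Input was not tested, and no biological explanation was tested.

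Macrophage genes rose with age in the captured RNA. More background RNA in O-coded captures is unlikely as the whole cause, since the Positive minus Input age difference was 0.05 for endothelial, -0.10 for fibroblast and 0.30 for rod genes (two-sided exact permutation tests, p = 0.739, 0.0563 and 0.0661; mean of the lists 0.0826, p = 0.333), and the rod value leaves a part to it open. For macrophage genes that difference was 0.844 (exact permutation test, p = 0.000408, the smallest possible over 2450 assignments). In Input alone macrophage genes were higher in O-coded pools by 0.191 (exact permutation test, p = 0.0322, adjusted p = 0.0552). The larger age difference in the Positive fraction argues against more macrophages in the O-coded tissue as the whole cause, if they raise both fractions alike. The test of that difference cannot decide where added macrophages are captured more than others, so more macrophages in that tissue remain open. Numbering block remains open, since age is nested in the blocks and blocks of 1 age differed by up to 0.361. Age, the biological explanation in the design, was not excluded.

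Melanin synthesis genes fell with age. A lower share of RPE in the O-coded pools is unlikely as the whole cause, since visual cycle genes differed by 0.0656 (exact permutation test, p = 0.436) and the difference between the lists was -0.964 (p = 0.000408, exact permutation test). Visual cycle genes went both ways and the mean rested on Rbp4, but without it the difference was -0.113, no gene of 11 fell by more than 0.371, and melanin synthesis genes fell by 0.785 more (p = 0.000816, exact permutation test), which leaves a small part open. Numbering block remains open here too, with a difference of up to 0.293 between blocks of 1 age. Most melanocyte genes fell as well in both fractions, with Erbb3 higher in Input, as given above. Whether choroidal melanocytes were lost was not tested.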

How the results depend on the processing

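The alternatives without pools 1, 2 and 5 and those on age and sex were chosen after the header or the results were seen. The fit with no filter repeats the main fit, as the filter removed 0 genes, so its 110 values and 5 counts could not change. With an estimated correlation and with fry only the list test changes, so the list medians stay those of the fit used. Of 4102 values of single genes and lists 3805 kept direction and side of the threshold, 90 changed sign but missed the threshold in both fits, 79 gained the call (15 with fry, which tests against no change) and 121 lost it, and 7 changed sign with a call in at least 1 fit: Apoe (-0.025 with pool block, length and GC), the ciliary body median (-0.0359 upper quartile, -0.0205 stricter filter, -0.018, -0.00968 and -0.00200 without numbering block A, B or C) and complement for sex (-0.147 without pools 1, 2 and 5). Of 423 recomputed counts, totals and shares 346 moved by less than 1.5 times (counts) or kept direction and side of the threshold (totals and shares). Of 40 lists for Positive against Input 19 were called, 5 with an estimated correlation and 34 with fry. With pools as a block 4938 genes rose and 5252 fell for Positive against Input, age by fraction gave 574 and 352, and among the named genes and the lists of Positive against Input it changed the calls of Dct, Ednrb and the interneuron and MHC class I lists and no other. DESeq2 gave 424 and 421 for sex in the Positive fraction, 590 and 294 in Input, 1 for age by sex and 117 lower for age by fraction; limma-voom gave 96 higher for sex in the Positive fraction and 260 lower in Input. Positive libraries alone gave 48 and 78 for sex. Numbering block as a covariate gave 591 and 801 for sex (456 of 456 calls kept) and 910 and 616 in Input. Without pools 1, 2 and 5, where fewer pools are compared and the lone OF pool is assumed to vary like the others, age gave 513 and 603 (150 at least 2-fold higher), 98 and 212 in Input, sex 81 and 321, 15 and 6 in Input, and age by fraction 52 and 25. The cause was not tested for these changes. Leaving out 1 pool gave 4231 to 4362 higher and 4586 to 4695 lower for Positive against Input (at least 2-fold 201 to 228 and 1569 to 1607), 907 to 1724 and 859 to 1594 for age in the Positive fraction (317 to 443 and 97 to 135), 645 to 1330 and 691 to 1420 in Input, 77 to 551 and 125 to 721 for sex, 134 to 634 and 50 to 350 in Input, 105 to 233 and 28 to 87 for age by fraction, and 0 to 0 for age by sex. Lrp1 lost its call with length and GC corrected (adjusted p = 0.992). Scaling without mitochondrial genes (none in the table) and pseudocounts (for counts not needed) were not run. Counts of at least 50 in a condition bound what depth could limit, and rarer transcripts were not analysed here.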

Other observations

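The genes of this part were chosen after their values were seen. Outside the gene lists, several genes known from tissue-resident macrophages rose with the O code in the Positive fraction but were not past the threshold in Input: Lyve1 (2.19 ± 0.266; Input 0.53), Folr2 (2.11 ± 0.220; Input 0.41), F13a1 (2.06 ± 0.219; Input 0.43) and the phospholipase gene Pla2g2d (2.24 ± 0.235; Input 0.20), and the age by fraction difference passed for Lyve1 (1.66, adjusted p = 0.00838), Folr2 (1.69, adjusted p = 0.00178), F13a1 (1.63, adjusted p = 0.00273) and Pla2g2d (2.04, adjusted p = 0.000752). Their levels were low, 7.53 and 1.67 CPM for Lyve1 in O-coded and Y-coded Positive libraries (7 and 8 libraries). The largest age by fraction differences were of the neuropeptide gene Npy (2.71 ± 0.390), which rose from 0.845 to 11.9 CPM in Positive libraries, the amine oxidase gene Aoc3 (2.61 ± 0.606) and the synuclein gene Sncg (2.34 ± 0.610). Cd5l, a macrophage gene, fell with the O code in Input (-1.45) and was not past the threshold in the Positive fraction (0.50, adjusted p = 0.0584). As for all age results, numbering block and age cannot be told apart.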
